A study of Mus musculus with 6 samples.

How the data were processed

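Enhanced reduced representation bisulfite sequencing, which reads cytosine methylation in DNA fragments cut by the enzyme MspI, was applied to 6 mouse libraries in 3 groups of 2. The groups were wild-type hematopoietic stem cells (HSC), wild-type MPP, the differentiation-committed progenitors of the series, and HSC without a functional Satb1 gene (Satb1-null). Per the labels' protocols, fetal liver cells of either genotype were transplanted into irradiated recipients, donor-derived cells were sorted from a pool of 3 animals, 10 ng of DNA was digested, fragments of 150 to 400 bp were selected, and the libraries were sequenced as 50 bp single-end reads. The p-values therefore rest on the spread between 2 pools per group, not between single animals. That spread was largely taken over all tiles or sites together, as described below.

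Per the submitters' processing notes, CASAVA 1.8, Bismark and methylKit were used and the build was mm9. The versions of the last 2 tools and the treatment of duplicate reads are not given in the sources used here. The deposited coverage is a count of reads at 1 CpG cytosine on 1 strand, and per the file headers each position also has the percent of reads with C (methylated) and with T (unmethylated). No position was below a coverage of 10 in any library, so a lower minimum could not be tried. The percentages were turned back into whole reads, and reads that were neither C nor T were left out of the levels. The reads carry no molecular identifiers, so they are not independent molecules.

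Of 3053323 positions held by any library, 1144708 were held by all 6 and were used for every comparison. Their methylated and unmethylated reads were summed over tiles of 1 kb (1000 bp) with at least 3 such positions, which gave 86146 tiles with a median of 5 sites and of 442 reads per library. The main test was a quasi-binomial logistic model with all 6 libraries in 1 fit (3 residual degrees of freedom). Its dispersion came from the Pearson statistic within groups, moderated with limma 3.58.1 (squeezeVar at its default settings) in R 4.3.3 and kept at or above 1. An F test of each contrast followed, with Benjamini-Hochberg adjustment over all tiles. A tile was called at an adjusted p under 0.05 and a difference of pooled group levels of at least 10 percentage points. Single CpG sites were tested in the same way with a minimum of 25 points, and there the moderation gave every site 1 common dispersion of 4.73. This design, the main list of other settings and the rule for named tiles were fixed before the data were examined. The rule takes, for MPP and for Satb1-null HSC against wild-type HSC, up to 10 called tiles with the largest rise and 10 with the largest fall whose libraries lie on one side of the other group's.

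The moderation of the dispersion decides how many tiles are called, and 6 forms of it were run. The first is the one fixed beforehand, which is reported. The other 5 were added after its counts had been seen: the robust setting of squeezeVar, a prior that follows coverage, both together, the larger of the flat and the coverage-following dispersion, and the larger of these and the tile's own. The last 2 called 0 tiles in every comparison. In the simulations below they recovered 0 of 100 tiles changed by 40 points between MPP and HSC where the dispersion follows depth. They recovered 69 and 63 with the moderated dispersions of the tiles, and 45 and 32 where it varies at random. The fixed form recovered 34, 79 and 57. Its false calls numbered 7, 54 and 29. Those of the last 2 forms numbered 0 and 0, 8 and 4, and 14 and 8. Limma on log2 ratios, put through the same simulations later, recovered 2, 0 and 0, so its 0 calls say little. None replaced the fixed form.

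The test was run on simulated tiles at the real depths, with 200 changed tiles. These were drawn only from tiles with a middle pooled level over the 6 libraries. With counting noise only, it recovered 100 of 100 tiles changed by 40 points between MPP and HSC, with 1 false call. With noise between libraries the result depended on how that noise was drawn. The first version drew it from the moderated dispersions of the tiles and gave 54 false calls among 165 for the MPP comparison. The other forms were added after that result. The one with a dispersion that follows depth gave 7 false calls among 44 and recovered 34 of 100. With no change at all, 5 draws each gave 22 to 28 calls in the first form, 0 to 5 in the second, and 1 to 14 when the dispersion varied at random. For Satb1-null against wild-type HSC the false calls were 34 among 166 in the first form and 14 among 88 in the second. Where the dispersion varied at random, they were 29 among 94 for MPP and 99 among 210 for Satb1-null HSC. At single sites with 200 changed, false calls for the MPP comparison numbered 186, 1342 and 0 with a dispersion that follows depth, varies at random or is absent. The adjusted p-values of tiles and sites are therefore too small where libraries vary, and the counts of calls are to be read with these numbers.

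Low, intermediate and high classes are means over the 6 libraries under 20%, from 20% to 80%, and from 80%. The relation between comparisons that share the wild-type HSC libraries was set beside 20 simulated draws with no group effect. Replicate numbers were not used in the main test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No annotation of mm9 was used here and coordinates were not converted, so tiles are named by mm9 position, and the planned promoter tests, gene lists and the Satb1 locus were not analysed here.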

Results

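DNA methylation was measured at CpG sites in wild-type HSC, wild-type MPP and Satb1-null HSC, with 2 libraries per group. HSC are the blood-forming stem cells, MPP are the multipotent progenitors next to them, sorted without the surface marker CD150 that marks the HSC here, and SATB1 is a chromatin-organizing protein that binds AT-rich DNA. The coverage summed over sites was 85161324 reads in wild-type HSC replicate 1 and 244784639 in replicate 2, 95427963 and 80817836 in the MPP replicates, and 162146102 and 204132355 in the Satb1-null replicates. The median coverage of a site lay between 44 and 97 reads. Wild-type HSC replicate 2 held 2177247 sites and Satb1-null HSC replicate 2 held 2178665, against 1474867 to 1681312 in the other libraries. Across sites, log coverage correlated at r = 0.72 between these 2 libraries and at -0.12 to 0.21 between either of them and the other 4. Their site methylation levels correlated at 0.973, below the 0.984 between wild-type HSC replicate 2 and Satb1-null HSC replicate 1. Coverage therefore set the pair apart, and this correlation of levels did not. Over the sites held by all libraries, the read-weighted level was 32.5% and 32.9% in the pair and 24.7% to 28.0% in the others. With sites weighted alike it was 31.5% and 31.4% in the pair and 29.8% to 31.4% in the others. The labels name no batch, and this pair is treated below as a library class.

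The first question was whether overall methylation differs between the groups. The mean level over the sites held by all libraries was 30.9% ± 0.80 in wild-type HSC, 30.6% ± 1.10 in MPP and 31.0% ± 0.54 in Satb1-null HSC (SD, n = 2 each). MPP minus wild-type HSC was -0.33 points and Satb1-null minus wild-type HSC was 0.10 points, both smaller than the pooled SD within groups of 0.84 points. The first depended on the weighting, with -1.94 points read-weighted. It also depended on the sites, with -7.29 over every site a library holds, a set that differs between libraries. The second difference was 0.91 and 0.30 points in these 2 settings. Without wild-type HSC replicate 1 the 2 differences were -0.90 and -0.46 points, and without replicate 2 they were 0.23 and 0.67. The first was -1.11 and 0.44 without MPP replicate 1 and 2, and the second 0.48 and -0.28 without Satb1-null replicate 1 and 2, so neither direction was kept. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333. Low sites made up 64.5% of the sites, intermediate sites 7.38% and high sites 28.1%. At high sites the level was 93.6% ± 0.88 in wild-type HSC, 92.1% ± 3.94 in MPP and 93.8% ± 1.37 in Satb1-null HSC (SD, n = 2 each), and MPP replicate 2 had 89.3% against 94.9% in MPP replicate 1. On the X chromosome wild-type HSC replicate 1 had 45.8% and replicate 2 had 54.7%, a gap within the group that exceeded every difference between group means.

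**Figure D1:**
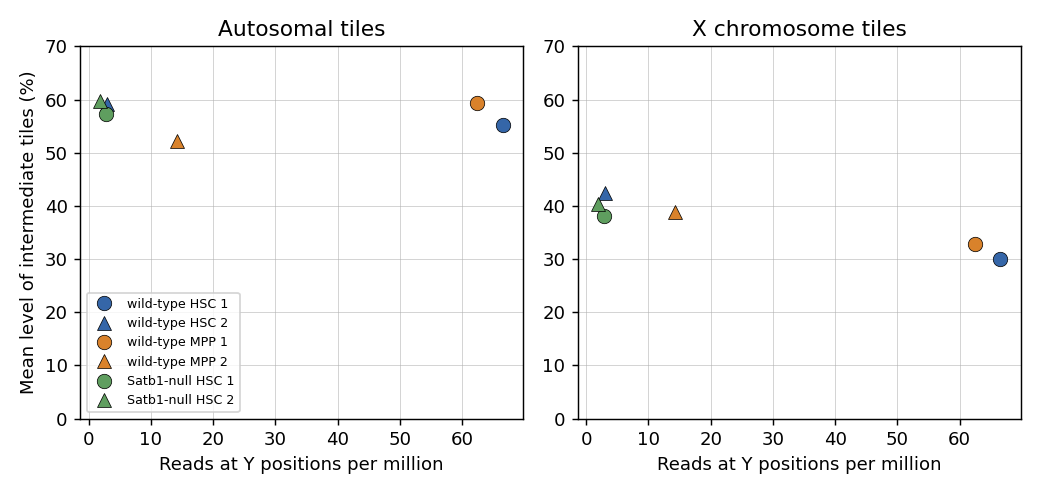
Mean methylation level (percent) of intermediate tiles on autosomes (left) and on the X chromosome (right) against reads at Y positions per 1000000 reads, 1 point per library. On X, wild-type HSC replicate 1 at 30.1% and MPP replicate 1 at 32.9% lie below the other 4 libraries, at 38.2% to 42.4%, and on autosomes they do not.

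The second question was which regions change methylation between wild-type HSC and MPP. Of 86146 tiles, 18 passed the threshold, 10 with a higher and 8 with a lower level in MPP. The rises were between 26.0 and 48.5 points and the falls between 20.7 and 64.5 points. These differences are between levels pooled over the reads of a group, while values with ± are means of the 2 libraries. The tile with the smallest adjusted p lay on chromosome 8, from 91151001 to 91152000, with 50 CpG sites. Its level was 44.2% ± 2.76 in wild-type HSC and 69.8% ± 4.86 in MPP (SD, n = 2 each), on 2320 to 5781 reads per library, with an adjusted p of 0.00176 (limma-moderated F test). A tile with 58 sites on chromosome 6, from 52154001 to 52155000, had 48.9% ± 15.1 in wild-type HSC and 78.8% ± 1.08 in MPP, with an adjusted p of 0.00557 in the same test and 2849 to 6561 reads per library. The largest rise, 48.5 points, was at chromosome 7, 74588001 to 74589000, where the pooled level was 16.6% in wild-type HSC and 65.1% in MPP and the means were 19.2% ± 10.2 and 65.0% ± 3.71. On chromosome 12, from 109457001 to 109458000, the 2 wild-type HSC libraries had 49.9% and 49.3% and the MPP libraries 81.5% and 74.9%. Other rises were on chromosome 19 at 23211001, chromosome 7 at 25162001, chromosome 11 at 120102001, chromosome 5 at 108150001 and 98364001, and chromosome 8 at 124833001, the last from 4.55% ± 2.54 to 34.3% ± 3.86.

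The largest fall was at chromosome 11, 118867001 to 118868000, a tile with 4 CpG sites. Its pooled level was 68.0% in wild-type HSC and 3.56% in MPP, and the means were 61.9% ± 13.8 and 2.86% ± 2.72 (SD, n = 2 each), on 107 to 828 reads per library. At chromosome 10, 61214001 to 61215000, it was 59.6% ± 5.32 in wild-type HSC and 13.9% ± 5.05 in MPP, with an adjusted p of 0.00557 (limma-moderated F test). At chromosome 7, 20430001 to 20431000, the levels were 46.9% ± 5.78 and 4.82% ± 1.24. The other falls were on chromosome 17 at 80538001, chromosome 19 at 41113001, chromosome 7 at 86460001 and chromosome 11 at 51457001 and 87570001. In 7 of the 8 tiles that fell, the pooled MPP level was under 20%. In all 18 tiles both MPP libraries lay on one side of both wild-type HSC libraries, which chance gives in 33.3% of unselected tiles.

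**Figure D2:**
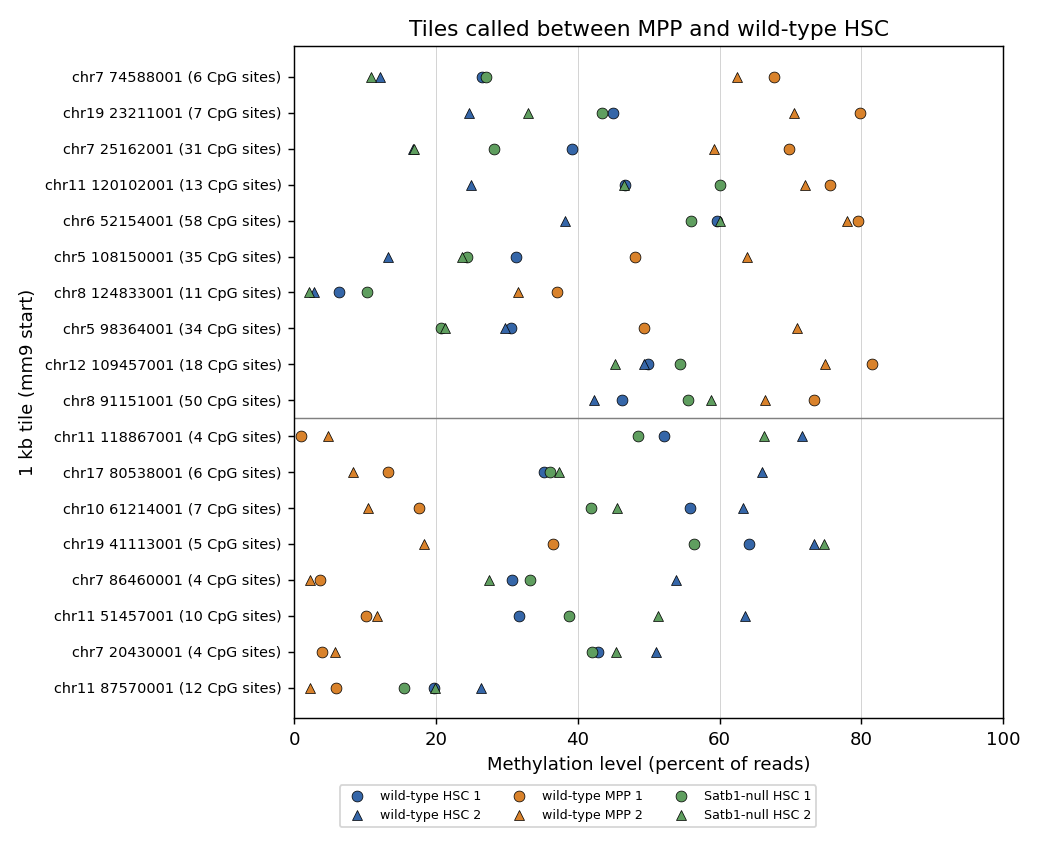
Methylation level (percent of reads) of each library at the 18 tiles called between MPP and wild-type HSC, with rises above the line and falls below it, sorted by size. Circles are replicate 1 and triangles replicate 2. MPP libraries lie apart from both wild-type HSC libraries in each tile, and Satb1-null HSC lie nearer to wild-type HSC in 16 of 18.

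The count of 18 is fragile. Simulated libraries with no group effect gave between 0 and 28 calls in this comparison, depending on how the noise was drawn, so the count alone does not separate it from no effect. The count was 780 without wild-type HSC replicate 1, with 267 higher and 513 lower in MPP. It was 50 without wild-type HSC replicate 2, with 47 higher and 3 lower, 267 without either Satb1-null replicate, with 126 higher and 141 lower, and 1 without MPP replicate 2. The balance of rises and falls therefore depends on the libraries used. No tile was called with tiles of 5000 bp, nor with 2 forms of dispersion added after seeing the data. These forms recovered 0 of 100 simulated tiles changed by 40 points with a dispersion that follows depth. They recovered 69 and 63 with the moderated dispersions of the tiles, and 45 and 32 with one that varies at random. The reported form recovered 34, 79 and 57. In the last 2 simulations these forms made 8 and 4, and 14 and 8 false calls, against 54 and 29 in the reported form. The count was 48 at a coverage minimum of 20, 28 on autosomes only, 68 with tiles of 500 bp and 319 with at least 1 common site. Limma on log2 ratios called 0 tiles, with 3095 at an unadjusted p under 0.05 against 3665 in the main test, but recovered at most 2 of 100 tiles changed by 40 points where simulated libraries varied. Within the libraries of the smaller site number, where wild-type HSC have 1 library, it was again 50, with 47 higher and 3 lower. With a term for the library class it was 41, with 29 higher and 12 lower, and 14 of these were among the 18.

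The third question was whether loss of Satb1 changes methylation in HSC. No tile passed the threshold. With the limma-moderated F test the smallest adjusted p was 0.197, and 4648 of 86146 tiles (5.40%) had an unadjusted p under 0.05. Limma on log2 ratios also called 0 tiles, with 2564 at an unadjusted p under 0.05, but it recovered at most 5 of 100 tiles changed by 40 points where simulated libraries varied. Other settings did call tiles: 5 at a coverage minimum of 20, with 2 higher and 3 lower in Satb1-null HSC, 10 with tiles of 500 bp, with 4 higher and 6 lower, and 135 with at least 1 common site, with 64 higher and 71 lower. A prior dispersion that follows coverage, added after seeing the data, called 10, with 3 higher and 7 lower. Simulated libraries with no group effect gave between 0 and 34 calls in this comparison with the main test. The 5 tiles with the smallest p were looked up after the test. At chromosome 17, 55409001 to 55410000, the level was 94.9% ± 1.16 in wild-type HSC and 63.5% ± 6.24 in Satb1-null HSC (SD, n = 2 each), on 134 to 760 reads per library. At chromosome 9, 107202001 to 107203000, it was 73.4% ± 8.38 and 91.0% ± 3.44. At chromosome 17, 26576001 to 26577000, it was 74.8% ± 5.0 and 59.8% ± 0.62, and at chromosome 5, 112698001 to 112699000, 36.9% ± 4.97 and 66.1% ± 18.9. The fifth was the chromosome 8 tile at 91151001, with 57.2% ± 2.33 in Satb1-null HSC.

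Each library class holds 1 wild-type and 1 Satb1-null HSC library. With a term for the class, 118 tiles were called, 62 higher and 56 lower in Satb1-null HSC. When the genotypes were exchanged within 1 class, 86 tiles were called. The class with fewer sites alone gave 32 tiles, 31 higher and 1 lower. That is 1 library against 1, and the spread comes from the 2 MPP libraries alone. The class with more sites holds 1 library per genotype and no MPP, which leaves no spread to test against. The count without the term was 360 without wild-type HSC replicate 1, with 127 higher and 233 lower, and 122 without wild-type HSC replicate 2, with 104 higher and 18 lower. It was 193 without Satb1-null replicate 1, with 108 higher and 85 lower, and 84 without Satb1-null replicate 2, with 31 higher and 53 lower. Simulated tiles were changed at middle levels only, while low and high tiles made up 30.9% and 54.8% of those tested. The simulated libraries also lack the deviation shared by wild-type and Satb1-null HSC replicate 2, so recovery in the real data may differ. With a dispersion that follows depth, 60 of 100 tiles changed by 40 points were recovered and 14 of 100 changed by 20 points. These numbers were 90 and 42 with the moderated dispersions of the tiles, 86 and 25 with a dispersion that varies at random, and 100 and 99 with counting noise only.

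Satb1-null HSC were also compared with MPP directly. Of the tiles, 10 passed, 9 lower and 1 higher in Satb1-null HSC. The smallest adjusted p, 0.00106 in the limma-moderated F test, was at chromosome 5, 98364001 to 98365000, with 60.1% ± 15.3 in MPP and 21.0% ± 0.42 in Satb1-null HSC (SD, n = 2 each). The single tile with a higher level, at chromosome 4, 86358001 to 86359000, named after its values were seen, had 27.3% ± 28.4 in MPP and 90.9% ± 6.04 in Satb1-null HSC. Of the 10 tiles, 4 were among the 18 that separate MPP from wild-type HSC. Simulated libraries with no group effect gave between 0 and 36 calls in this comparison, so the count alone does not separate it from no effect. No tile was called with tiles of 5000 bp, with the same 2 added forms of dispersion, or with limma on log2 ratios, where 2688 tiles had an unadjusted p under 0.05 against 3109 in the main test. The lean to lower levels was not kept throughout. The count was 231 without either wild-type HSC replicate, with 118 higher and 113 lower in Satb1-null HSC, and 581 without Satb1-null replicate 1, with 367 higher and 214 lower. It was 38 without Satb1-null replicate 2, with 8 higher and 30 lower, 20 without MPP replicate 1, with 7 higher and 13 lower, and 0 without MPP replicate 2. With a term for the library class it was 51, with 9 higher and 42 lower. Within the class with fewer sites, where Satb1-null HSC have 1 library, it was 47, with 11 higher and 36 lower.

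At single CpG sites, 636 of 1144708 passed between MPP and wild-type HSC, 197 higher and 439 lower in MPP. Between Satb1-null and wild-type HSC 642 passed, 343 higher and 299 lower. A coverage minimum of 20 gave 559 and 287 sites. A replicate block gave 0 in both comparisons, with 19848 and 29475 sites at an unadjusted p under 0.05 in its F test. The recovery of that fit was not simulated, so its 0 says little. In simulated data with changed sites in the other comparison only, the main test made calls as well. With a dispersion that follows depth they numbered 131 for MPP and 151 for Satb1-null HSC. With one that varies at random they numbered 1251 and 1238, so the count of sites does not separate either comparison from no effect. For MPP it was 1675 without wild-type HSC replicate 1, with 504 higher and 1171 lower, and 254 without MPP replicate 1, with 25 higher and 229 lower. The direction turned without wild-type HSC replicate 2, with 57 higher and 20 lower of 77, and without MPP replicate 2, with 54 higher and 47 lower of 101. For Satb1-null HSC the split was 691 higher and 937 lower of 1628 without wild-type HSC replicate 1, and 160 and 139 of 299 without either MPP replicate. It was 1279 and 1189 of 2468 without Satb1-null replicate 1, and 18 and 178 of 196 without Satb1-null replicate 2. Without wild-type HSC replicate 2 it was 393 higher and 82 lower of 475.

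The last comparison set the tile differences of MPP against those of Satb1-null HSC, each taken from the same wild-type HSC libraries. Across tiles, which are not independent replicates, Pearson's r was 0.473 and Spearman's rho 0.433, and 65.7% of tiles had the same sign. Simulated data with no group effect gave 0.445 ± 0.0058, 0.387 ± 0.0039 and 64.2% ± 0.14 (SD over 20 draws). The real values lay above the simulated ones by more than the SD over draws. On leaving out 1 library, r was 0.634 and 0.736 without wild-type HSC replicate 1 and 2. It was 0.302 and 0.469 without MPP replicate 1 and 2, and 0.221 and 0.570 without Satb1-null replicate 1 and 2. No draws were simulated with a library left out, so these values of r cannot be set against the gap. The covariance, to which shared libraries add the same amount with or without an effect, was 11.6 squared points against 11.9 ± 0.21 in the simulated data. The simulated libraries leave out the deviation that wild-type HSC replicate 2 and Satb1-null HSC replicate 2 have in common. A deviation common to both HSC groups lowers this covariance, so the higher r is not traced to it. The real covariance was not above the simulated one. The gap in r is therefore not read as a relation beyond the shared libraries, and such a relation is not excluded either. The overlap of calls cannot be assessed, because no tile was called for Satb1-null HSC.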

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

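The tests on X chromosome levels in this part were chosen after the levels per library had been seen. Reads at Y positions, which no comparison used, numbered 5667 in wild-type HSC replicate 1, 742 in replicate 2, 5959 in MPP replicate 1, 1155 in MPP replicate 2, 461 in Satb1-null replicate 1 and 392 in Satb1-null replicate 2. Per 1000000 reads this was 66.5 and 62.4 in wild-type HSC replicate 1 and MPP replicate 1 and 1.92 to 14.3 in the others. In the 2 libraries with the most Y reads, intermediate X tiles lay lower than in the other 4 by more than intermediate autosomal tiles did, with an extra shift of -8.64 points. A shift of the whole library is argued against, since the autosomal shift was 0.17 points, or -2.02% of the X shift. A larger share of male donor cells, which carry no inactive X, is a candidate explanation that calls for both the Y reads and the lower X level. The relation was not graded. MPP replicate 2, next with 14.3 Y reads per 1000000, had X minus autosomal intermediate tiles at -13.4 points. In the other libraries this difference was -16.8 to -26.5 points. The exact permutation p (one-sided, 2 of 6 libraries) is 0.0667, the smallest that 6 libraries allow. No label gives the sex of the animals. Both groups of wild-type cells hold 1 such library, and neither Satb1-null library is one.

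The share of reads that were neither C nor T, also outside the comparisons, was 0.430% in wild-type HSC replicate 1, 0.0754% in replicate 2, 0.0228% in MPP replicate 1, 0.445% in MPP replicate 2, 0.0262% in Satb1-null replicate 1 and 0.0737% in Satb1-null replicate 2.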

How the results depend on the processing

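Counts are given for MPP against HSC, Satb1-null against wild-type HSC and Satb1-null HSC against MPP, in that order, beside 18, 0 and 10 tiles. The cause of a changed count was not tested. Limma recovered 0 to 2 of 100 simulated tiles changed by 40 points between MPP and HSC where libraries vary, so its 0 is not evidence of no change. Planned settings gave 48, 5 and 32 with a coverage minimum of 20; 6307, 3571 and 5690 with no overdispersion; 0, 0 and 0 with limma on the log2 ratio and with tiles of 5000 bp; 68, 10 and 43 with tiles of 500 bp; 319, 135 and 175 with at least 1 common site; 28, 0 and 16 on autosomes only. With only the 4 libraries compared, the counts were 267, 0 and 231. A replicate block gave 0, 0 and 0 tiles, and 0 single sites in both comparisons. At single sites this fit had only 0.80 prior degrees of freedom. Its recovery was not simulated, so its 0 is not evidence of no change. Over intermediate tiles, replicate 2 minus replicate 1 correlated at 0.278 between wild-type and Satb1-null HSC. It correlated at 0.0476 between wild-type HSC and MPP and at -0.0347 between MPP and Satb1-null HSC. The replicate numbers therefore go with the library class in HSC, but they do not pair the MPP libraries with the HSC libraries. No minimum difference, 25 points, and leaving out the top 0.1% of coverage kept the counts within 1.5 times. Leaving out 1 library gave 1 to 780, 0 to 360 and 0 to 581 tiles; a group left with 1 library is assumed to vary like the others.

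These alternatives were chosen after seeing the data. A prior dispersion that follows coverage called 51, 10 and 26 tiles, of which 14 were among the 18. The robust setting called 18, 0 and 5, sharing 10 of the 18, and both together 49, 9 and 23. The larger of the flat and the trended dispersion, with or without the tile's own, called 0, 0 and 0. A term for the 2 libraries with the most sites gave 41, 118 and 51, and without them 50, 32 and 47. Without the 2 libraries with the most Y reads the counts were 493, 330 and 290, and without the 2 with the most reads neither C nor T 513, 330 and 90. Weighting sites alike kept 18, 0 and 10.

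Single sites, beside 636 (MPP) and 642 (Satb1-null), were 15520 and 9157 with no overdispersion, 287 for Satb1-null with a coverage minimum of 20, and 77 to 1675 and 196 to 2468 without 1 library. Mean methylation, MPP minus HSC, was -1.94 points read-weighted and -7.29 over every site a library holds, and -1.11 to 0.44 without 1 library; Satb1-null minus wild type was -0.46 to 0.67 without 1 library. The correlation of tile differences was 0.484 with tiles of 5000 bp, 0.461 at a coverage of 20, 0.481 on the log2 scale, and 0.221 to 0.736 without 1 library. Of 161 values of the 18 named tiles under settings fixed beforehand, 84 kept the call. The other 77 lost it, with adjusted p up to 1 for each tile, and kept the direction: all 18 under limma, where the difference is the same by construction, all 18 under the replicate block, with 0.89 to 1.01 times the difference, 17 without MPP replicate 2, and 12 each without MPP replicate 1 and wild-type HSC replicate 2. The difference stayed within 1.5 times in 16 of the 17, in all 12 without MPP replicate 1 and in 7 of the 12 without wild-type HSC replicate 2, where the lowest was 0.47 times. Promoter and gene list alternatives were not run, since no annotation of mm9 was used.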

Other observations

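Tests on the shared deviation of the 2 replicate 2 libraries, except the weighting of sites, and the tests on CpG numbers, neighbouring tiles and other pairings were chosen after the result was seen. The 10 tiles that rose in MPP held a median of 24.5 common CpG sites and the 8 that fell a median of 5.5. The median was 5 in all tiles (exact permutation test of mean log2 number of sites, rises against falls, two-sided p = 0.00238). This test treats the tiles as independent, although the same libraries gave all of them and the balance of rises and falls changed with the libraries. Its p-value therefore describes these tiles only. Of 31 uncalled tiles within 5 kb of a called one, 20 differed in its direction (64.5%), by 3.04 points on average. Around 2000 random intermediate tiles the values were 52.6% and 0.49 points. The random tiles were not matched to the called ones in size of difference, and the gap was not tested.

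Wild-type HSC replicate 2 and Satb1-null HSC replicate 2 share methylation differences from the other HSC libraries. Set against wild-type HSC replicate 1 and Satb1-null replicate 1 this pair gave 1168 called tiles, 939 higher and 229 lower, far more than any real comparison. For example, at chromosome 2, 118503001 to 118504000, both had 44.8% and 44.0% where the other 4 libraries had 5.77% to 13.3%. Reads falling on different fragments of a tile are argued against as the whole cause, since 56.6% of the tiles kept 10 points with every site weighted alike, although the median difference was then 0.639 of the read-weighted one, so part of the size stays open to it. Donor sex is argued against as the cause of most of these tiles, since 1092 of the 1168 (93.5%) were autosomal. That share is below the one among all tiles tested, 84062 of 86146, so sex stays open for the tiles off the autosomes. Also argued against are chance copies of few molecules, since the 2 libraries' deviations correlated at 0.278 over intermediate tiles. A shared sort, day or preparation cannot be told apart from other causes, because the labels name none.

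At the 18 tiles called between MPP and wild-type HSC, Satb1-null HSC lay a median of 0.171 of the way from wild-type HSC to MPP, and between both groups in 16 tiles. Part of this may come from the reuse of the wild-type libraries. No tile passed for MPP against all 4 HSC libraries. The 18 tiles with the smallest p and at least 10 points there were taken instead, a choice made once 0 had passed. The median share was 0.00127 for the real Satb1-null pair. This low share met the prediction written beforehand for reuse, though at tiles that had not passed. Of the 6 ways to pick 2 of the 4 HSC libraries, 3 gave a share as high, the real pair among them. The highest, 0.276, was wild-type HSC replicate 1 with Satb1-null replicate 1, the HSC libraries of the class with fewer sites, so library class enters. Each pair's share mirrors that of the remaining pair with the sign turned, so the rank adds nothing to the real share itself. A shift toward the progenitor state by Satb1 loss therefore stays open only as a hypothesis without support from this test.

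Of 45 comparisons between pairs in the 15 ways to pair the libraries, the 6 that set the replicate 2 HSC pair against another gave 939 to 1701 tiles. Of 36 others that are neither these nor the real groups, 3 gave 18 or more, and the median of the 36 was 1. The highest, 62, set MPP against wild-type HSC replicate 1 with Satb1-null replicate 1, the HSC libraries of the class with fewer sites. The others, 40 and 31, both held wild-type HSC replicate 1 with MPP replicate 1, the pair with the most Y reads. These 3 also hold cell type or library differences, so they are no background without effect for the count of 18.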
